A study of Mus musculus with 2 samples.

How the data were processed

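CUT&RUN maps where a protein sits on chromatin: an antibody brings a nuclease to its target, the nuclease cuts the DNA around it, and the released fragments are sequenced. Per the labels, chromatin of wild-type CD1 mouse retina at embryonic day 14 was profiled with an antibody against the POU-domain transcription factor POU3F1 in 1 library and with rabbit IgG, which has no target in mouse chromatin, in 1 library. Per the labels' protocols, DNA was purified on columns, libraries were made by adapter ligation and PCR and size-selected on beads, and sequencing was paired-end on a NovaSeq instrument. The number of embryos and their sex are not given in the sources used here.

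The submitters' processing notes name Bowtie2, MACS2 and deepTools, without versions, and the mouse build mm10. The authors' deposited peak list held 2652 intervals in the MACS2 narrow-peak layout. For each interval it gave a fold enrichment at the summit over the local background (a ratio), the −log10 of the p-value and of the q-value at the summit, and a score. The score, as deposited by the authors, is 10 times the −log10 q-value without its decimals. These values are the authors' and were used only to describe, rank or filter peaks within this list. A deposited 3-column list held the same 2652 intervals. A deposited gene table paired 2323 genes with peaks in 4427 pairs and gave the signed distance from each peak to the transcription start site (TSS) of the gene. Per the file headers, it was made with GREAT 4.0.4 on mm10, which gives each gene a basal domain of 5000 bp upstream and 1000 bp downstream and extends it up to 1000000 bp to the domains of its neighbours, with curated domains included. The names of 3 genes had been turned into dates there and were not matched to a gene. The signal track of the IgG library was not analysed here, so no value of its own is given for it.

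Peaks were called once, on 1 POU3F1 library, so there was no replicate check and no test between the antibodies. Every test describes this one peak list, in which peaks and genes are not replicates. Library depth is unknown from the values used here. The depth behind each peak was recovered instead: MACS2 computes the fold as (pileup + 1) / (background + 1) and the p-value from a Poisson distribution, and for 2609 peaks (98.4%) a whole-number summit pileup gave the deposited −log10 p-value within 0.001. The median summit pileup was 19 fragments, with quartiles of 13 and 33. On 1994 simulated peaks the recovery found the pileup in 100%, and 0.1% of altered p-values were called whole.

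Coordinates are mm10, counted from 1. Gene positions came from a RefSeq gene table of GRCm38.p6, the same assembly, which gives gene bodies without strand, exons or sequence. Of the 2323 genes, 2184 matched it by symbol, 86 by a synonym and 53 not at all. Each distance was placed on its peak by finding the TSS and strand that put all distances of a gene onto peak midpoints, which placed 4307 pairs (97.3%) with 12 ambiguous, and gave 2507 peaks an assigned TSS. Because strand, exons and sequence were not used here, the location test counted peaks near either end of protein-coding genes in place of the TSS, exons and introns were not separated, and the motif and octamer tests chosen before the data were examined were not run.

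Peak location was tested on 2594 peaks of the autosomes and chromosome X with a two-sided permutation test of 1000 random placements of each interval on its own chromosome (overlap of at least 1 bp), adjusted by Benjamini-Hochberg over the features. Gene lists were fixed before the data were examined: 17 lists, from retinal cell classes, axon guidance, adhesion and transcription factor families to other cell types of the eye, unrelated tissue, ribosomal protein and histone genes. They were drawn from general knowledge, share some genes, and were not taken from these libraries. Of 21900 protein-coding genes, 2231 (10.2%) had an assigned peak. Each list was tested against random lists matched on locus length in 10 strata, since long or isolated loci collect more peaks, with an exact stratified permutation test (two-sided), adjusted by Benjamini-Hochberg over the 17 lists with a threshold of 0.05. On 400 simulated lists of 50 genes without enrichment and with long loci, 3.5% were called with strata and 17% without. Of lists with 2.5 times the hits, 100% were called. The simulated chance of a peak was set by the same 10 strata, with genes independent. The simulation therefore could not check length effects within a stratum or peaks shared by neighbouring genes. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and rates exact Poisson ones, which cover counting error only.

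Genes named in the text were chosen by a rule set before the data were examined: Pou3f1, the 10 peaks of highest fold, the 10 genes with the most peaks, all members of the contralateral and ipsilateral lists with a peak, and the 4 members with the strongest peaks of every other list. Genes named outside the rule are marked as chosen afterwards, and 1 gene that the rule selects is not reported here. Alternatives were a q-value under 0.01 or 0.001, autosomes and X alone, other overlaps, a 5 kb window, no strata or 20 strata, assignment of the nearest TSS within 50 kb or of peaks within 5 kb, and all annotated genes as background. Leaving out the contigs, Y and mitochondrial peaks, and leaving the histone genes out of the background, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.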

Results

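POU3F1 occupancy was profiled by CUT&RUN in retina of wild-type CD1 mouse embryos at day 14, an age at which retinal ganglion cells (RGCs), the neurons whose axons form the optic nerve, are being born. The data comprised 1 library with an antibody against POU3F1 and 1 with rabbit IgG. The series concerns the gene network of Pou3f1 in RGCs whose axons cross the midline to the contralateral side of the brain, so the comparisons ask where POU3F1 peaks lie and which gene groups they are assigned to. There were no replicates, and all folds are the authors' enrichment at the peak summit over the local background.

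POU3F1 peaks in the E14 retina were short, mostly modest in enrichment and mostly far from genes' start sites. The 2652 peaks had a median length of 352 bp (quartiles 255 and 493) and covered 1139025 bp together. Their median fold was 6.37, with quartiles of 4.91 and 8.84, and 497 peaks reached 10-fold, 116 reached 20-fold and 18 reached 50-fold. Of all peaks, 2584 had a q-value under 0.01 and 2439 under 0.001. The summit pileup was under 20 fragments in 51.5% of the 2609 peaks for which it could be recovered, so many single peaks rest on few fragments.

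**Figure D1:**
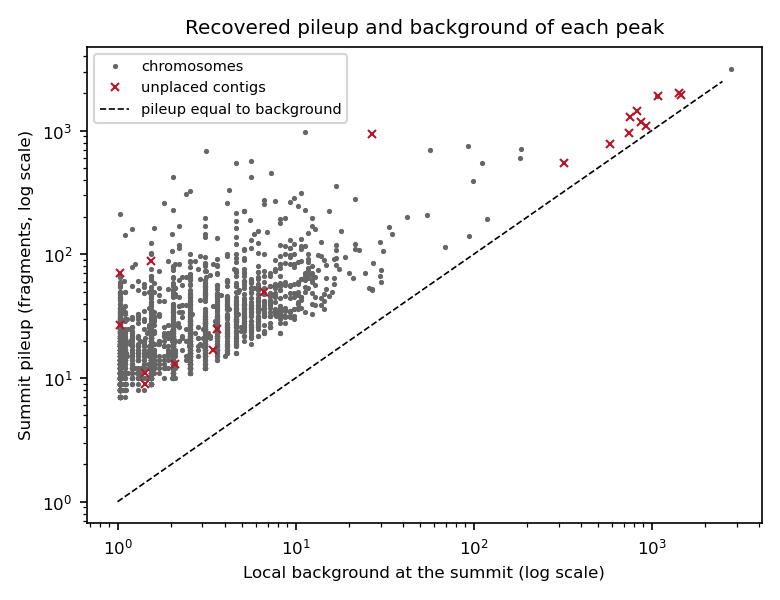
Summit pileup in fragments (y axis, log scale) against local background (x axis, log scale) for the 2609 peaks whose pileup was recovered, with peaks on unplaced or unlocalised contigs as crosses and equality of pileup and background as a dashed line. The column of points at the left is the 786 peaks at the lowest background, 1.04, and 20 contig peaks are shown, several close to the dashed line.

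The 10 peaks of highest fold lay near a mixed set of genes. The strongest (165.7-fold, summit pileup 682 fragments) was at chromosome 5: 109556932 to 109559092, inside Crlf2, a cytokine receptor gene, 981 bp downstream of its TSS. The next was at the promoter of Plppr2 (138-fold, chromosome 9: 21936389 to 21937438, 120 bp upstream). A peak of 104-fold at chromosome 2: 71529465 to 71530259 lay in Dlx1, 1749 bp downstream of its TSS, and was also assigned to Dlx2; both encode homeodomain factors of the developing retina and forebrain. The promoter of Fbxo47 had a peak of 96.9-fold (chromosome 11: 97883817 to 97884734). A peak of 92.4-fold at chromosome 11: 35454448 to 35455275 lay inside the gene of the secreted guidance ligand Slit3. Pank4 (91.0-fold), Rras (90.8-fold) and Gtpbp1 (86.1-fold) had peaks within 1 kb upstream of the TSS, and the remaining peaks were assigned to 2010315B03Rik (79.2-fold, 111716 bp upstream) and Tnks1bp1 (75.6-fold, 2592 bp upstream).

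Other loci stood out by number of peaks. Zfp608 had 28 assigned peaks, spread from 53993200 to 55944789 on chromosome 18, and Tmem161b had 26. The adjoining Mef2c, a neuronal transcription factor gene, had 19, all of them also assigned to Tmem161b. Tle4, a Groucho-type corepressor gene, had 17 peaks, and Dach1, a retinal determination gene, had 16 (strongest 73.4-fold). Erdr1 had 14, none of which could be placed on peaks of chromosome X, where alone they were sought. Chromosome Y also held 14 peaks, and whether they are those of Erdr1 was not examined. Adgrl2, Gm11232, Mdfic and Psat1 had 13 each. In contrast, 1441 genes had 1 peak. Counts of this kind depend on how far from the TSS peaks are assigned: within 50 kb of it, Zfp608 and Mef2c kept 1 peak each and Tmem161b none.

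By distance, 50 to 500 kb from the nearest assigned TSS held most peaks. It held 1473 of 2507 placed peaks, 58.8% (95% exact interval 56.8 to 60.7%), against 539 (21.5%) at 5 to 50 kb, 113 (4.51%) at 1 to 5 kb and 177 (7.06%, 6.09 to 8.13%) within 1 kb. Median fold was close in all classes, 6.96 within 1 kb and 6.37 at 50 to 500 kb, while the median summit pileup was 33 within 1 kb and 18 at 50 to 500 kb.

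**Figure D2:**
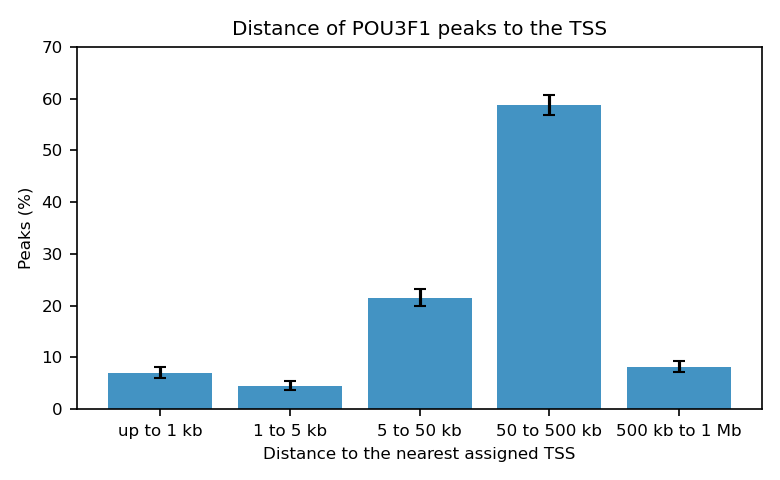
Share of the 2507 placed POU3F1 peaks (percent, y axis) by distance to the nearest assigned TSS (x axis), with 95% exact binomial intervals as error bars. The class of 50 to 500 kb holds 58.8% of peaks and the class within 1 kb holds 7.06%.

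Against random placement, peaks lay more often in annotated genes and in the immediate surroundings of gene ends. Random intervals could fall in assembly gaps and in sequence to which reads cannot be mapped, where no peak can be called. How much of these ratios comes from this was not tested. Bodies of protein-coding genes held 1268 of 2594 peaks (48.9%) against 40.4% for random intervals, a ratio of 1.21, and long non-coding RNA genes held 341, a ratio of 1.46. Peaks outside all annotated genes were fewer, 1043 against 1322 expected, a ratio of 0.789. Within 1 kb of an end of a protein-coding gene lay 203 peaks against 93.7 expected, a ratio of 2.17. Each of these permutation tests gave p = 0.0020, the smallest that 1000 placements allow (adjusted p = 0.00333). In a 5 kb window, which includes that of 1 kb, 349 peaks lay against 337 expected, a ratio of 1.04 (permutation test, adjusted p = 0.609). Beyond the excess within 1 kb, the rest of this window therefore held fewer peaks than random placement gave, a part not tested by itself.

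The contralateral and ipsilateral RGC lists did not pass the test. Of 18 contralateral genes, 8 had a peak against 4.60 expected from lists of matched locus length, a ratio of 1.74 (exact permutation test, adjusted p = 0.136), and of 21 ipsilateral genes, 6 had a peak against 4.36 expected, a ratio of 1.38 (exact permutation test, adjusted p = 0.596). The difference between the 2 lists was not tested. No gene of either list had a peak within 5 kb of its TSS, where matched lists gave 0.29 and 0.381 genes. Without matching on locus length both lists passed, with ratios of 4.36 (exact permutation test without strata, adjusted p = 0.00074) and 2.80 (same test, adjusted p = 0.0445).

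Among contralateral genes, the Pou3f1 locus itself had 2 peaks, at chromosome 4: 124616247 to 124616713 (8.35-fold, 40327 bp upstream of the TSS) and 124639693 to 124639929 (5.89-fold, 16996 bp upstream). Their summit pileups were 16 and 11 fragments. Pou4f1, which encodes an RGC transcription factor, had 4 peaks, the strongest at chromosome 14: 104356400 to 104357032 (19.7-fold, 111283 bp downstream). Sox4 and Sox11, SoxC factor genes of RGC development, had 9 and 6 peaks with strongest folds of 14.3 and 9.96, and Fgf12 had 2 (15.1-fold). Nrcam and Nrp1, whose products act in growth of crossing axons at the optic chiasm, had 2 peaks each, with strongest folds of 7.48 and 7.86. Tfap2d had 2 (8.84-fold), of which 1 remained at a q-value under 0.01. Within 50 kb of the TSS, Sox4, Sox11, Fgf12, Nrp1 and Tfap2d kept no peak, and Pou4f1 and Nrcam kept 1 each. Isl2, a contralateral RGC marker named after its values were seen, had no assigned peak.

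Among ipsilateral genes, Tenm3, an adhesion molecule that shapes ipsilateral mapping, had 9 peaks, the strongest at chromosome 8: 49235934 to 49237011 (26.1-fold, 561782 bp upstream). The netrin receptor gene Unc5c had 7 peaks, of which the strongest at 141540762 and at 141565635 on chromosome 3 had 6.39-fold each. Zic5 had 3 (strongest 14.7-fold), while Zic1 (7.66-fold), Fbxl7 (7.86-fold) and Lypd1 (6.88-fold) had 1 each. Within 50 kb of the TSS, Zic5 kept 1 peak, and Tenm3, Unc5c, Zic1, Fbxl7 and Lypd1 kept none. Zic2 and Ephb1, the best-known ipsilateral determinants and also named after their values were seen, had no assigned peak. Gene domains stop at those of their neighbours, so a peak assigned to a neighbouring gene can still lie near a gene without one.

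Several broader retinal and neuronal lists did carry more peaks than matched lists. In all, 10 of 17 lists passed, all above expectation. Retinal progenitor genes had the largest ratio after the histone list: 19 of 41 had a peak against 5.89 expected, a ratio of 3.23 (exact permutation test, adjusted p = 1.17e-06), and 5 of them had one within 1 kb of the TSS. Strong peaks among them were at the promoter of Gadd45a (40.5-fold, chromosome 6: 67037218 to 67037824, 115 bp upstream) and 496482 bp upstream of Nfia (33.4-fold). Sox9, also in the progenitor list, had 4 peaks (strongest 24.2-fold).

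RGC identity genes had a peak in 24 of 54 cases against 11.4 expected, a ratio of 2.11 (exact permutation test, adjusted p = 0.000154). Some members shared peaks, as Dlx1 with Dlx2 and Irx3 with Irx5, so this p-value rests on fewer independent units than genes. With peaks within 5 kb of the TSS alone, 4 genes had a peak, a ratio of 4.66 that did not pass (exact permutation test, adjusted p = 0.0585). Besides Dlx1, Dlx2 and Pou4f1, their strongest peak was at Barhl2 (20.2-fold, chromosome 5: 106471146 to 106472492, 13653 bp upstream). Pou4f2, required for RGC differentiation, had its stronger peak 2788 bp upstream of the TSS (10.9-fold, chromosome 8: 78439146 to 78439721). Amacrine and horizontal cell genes, markers of the interneurons of the inner retina, had a peak in 16 of 29 cases against 6.03, a ratio of 2.66 (exact permutation test, adjusted p = 6.88e-05). Barhl2 belonged to that list too; Bhlhe22 (16.9-fold), Ebf3 (16.2-fold) and Ebf1 (14.7-fold) followed.

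The POU and SOX transcription factor families passed as well. Of 15 POU genes, 9 had a peak against 3.59 expected, a ratio of 2.5 (exact permutation test, adjusted p = 0.00576), with the strongest at Pou4f1, in Pou2f1 (14.7-fold, 35839 bp downstream), at the TSS of Pou6f1 (14.2-fold, chromosome 15: 100599432 to 100600357) and at Pou4f2. Of 20 SOX genes, 9 had a peak against 4.14, a ratio of 2.17 (exact permutation test, adjusted p = 0.0220). Sox2, a progenitor factor gene, had 11 peaks (strongest 11.0-fold) and Sox6 had 5 (10.3-fold). Counting only the nearest TSS within 50 kb, 3 SOX genes had a peak, and the list no longer passed although its ratio was 3.26 (exact permutation test, adjusted p = 0.179).

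Notch pathway genes, which hold retinal progenitors back from differentiation, had a peak in 9 of 32 cases against 3.69 expected, a ratio of 2.44 (exact permutation test, adjusted p = 0.0189). Peaks lay at the promoters of the effector Hes5 (20.4-fold, chromosome 4: 154960463 to 154961039, 172 bp upstream, summit pileup 198) and the ligand Dll1 (12.1-fold, chromosome 17: 15375723 to 15376341, 56 bp upstream). Nrarp (13.3-fold) and Notch2 (9.33-fold) had 1 peak each, 5123 and 11363 bp downstream of the TSS. Peaks within 5 kb of the TSS alone covered 3 Notch pathway genes, a ratio of 6.68 that did not pass (exact permutation test, adjusted p = 0.0585).

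Genes of axon growth and contact passed too, mostly with distant peaks, like the peak list as a whole. Among all placed peaks, 58.8% lay 50 to 500 kb and 8.18% 500 to 1000 kb from the nearest assigned TSS. Of 88 axon guidance receptors and ligands, 31 had a peak against 17.5 expected, a ratio of 1.77 (exact permutation test, adjusted p = 0.000813); in 19 of the 31 the nearest peak was over 50 kb from the TSS. After Slit3, the strongest were in Epha3 (62.8-fold, chromosome 16: 63808878 to 63810579), at Robo1, a Slit receptor gene (36.0-fold, chromosome 16: 72699103 to 72699855), and at the promoter of Ephb4 (25.2-fold, 330 bp upstream). Of 49 neural adhesion genes, 34 had a peak against 18.2, a ratio of 1.87 (exact permutation test, adjusted p = 2.58e-05), with Tenm1 (32.4-fold), Tenm3, Lrrn3 (23.8-fold) and Lsamp (22.6-fold) strongest. With peaks within 5 kb of the TSS alone, 4 guidance genes had a peak, a ratio of 3.02 that did not pass (exact permutation test, adjusted p = 0.21). Counting only the nearest TSS within 50 kb, 12 guidance genes had a peak, a ratio of 3.07 that passed (exact permutation test, adjusted p = 0.00294). With assignment limited to 50 kb, 7 adhesion genes had a peak, and the list no longer passed although its ratio was 2.08 (exact permutation test, adjusted p = 0.177).

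Lists of other cell types and tissues gave a mixed picture. Pigment epithelium and lens genes passed, with 8 of 29 against 3.32 expected, a ratio of 2.41 (exact permutation test, adjusted p = 0.0220). Mitf, the master factor of pigment cells, had the strongest peak (19.0-fold), followed by Crybb2 (13.8-fold), Tyrp1 (11.8-fold) and Dct (10.8-fold); within 50 kb alone 3 genes had a peak, a ratio of 3.23 that did not pass (exact permutation test, adjusted p = 0.179). Photoreceptor precursor genes (4 of 23, ratio 1.48, Thrb 11.0-fold, Sall3 10.6-fold, Rorb 7.11-fold and Otx2 5.40-fold) had an adjusted p of 0.610 in the exact permutation test. Endothelial, blood and microglial genes (6 of 30, ratio 1.49, Ptprc 13.4-fold, Emcn 7.86-fold, Runx1 5.77-fold and Flt1 4.42-fold) had 0.494 in the exact test. Schwann cell and myelin genes had a peak in 1 of 22 cases, at Olig2, an oligodendrocyte-lineage gene (6.39-fold, exact permutation test, adjusted p = 0.761). Liver and muscle genes had one in 2 of 40, Apob (15.4-fold) and F9 (7.37-fold), with an adjusted p of 0.958 in the exact test.

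**Figure D3:**
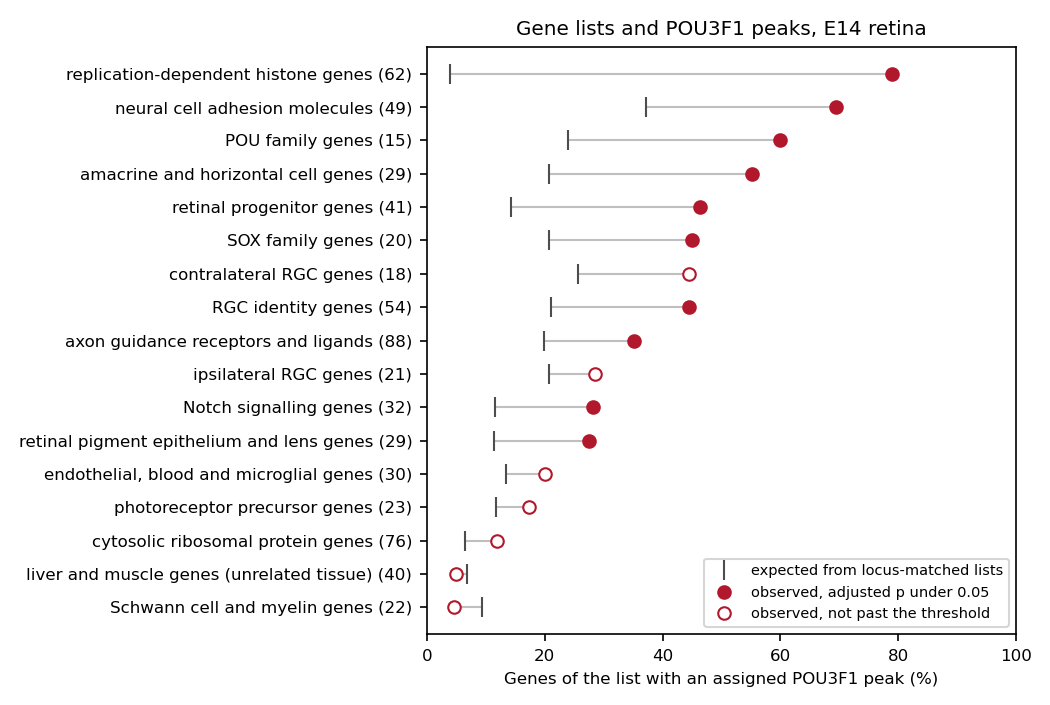
Share of genes with an assigned POU3F1 peak (percent, x axis) in each of 17 lists (y axis, number of genes in parentheses), with the share expected from lists of matched locus length as a vertical tick and the observed share as a dot, filled where the adjusted p was under 0.05. Histone genes stand at 79.0%, and Schwann cell and myelin genes and liver and muscle genes lie near or below their expectation.

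Replication-dependent histone genes, which supply histones in S phase, had a peak more often than any other of the 17 lists. Of 62 genes, 49 (79.0%) had a peak against 2.44 expected, a ratio of 20.1 (exact permutation test, adjusted p = 7.01e-59), and 37 had one within 1 kb of the TSS. Without matching on locus length the ratio was 7.76. Neighbouring histone genes share peaks, so genes were not independent units: 34 peaks lay within 5 kb of a histone gene, where random placement gave 0.489 (permutation p = 0.0020, the smallest possible, computed after the list result was seen). Their median fold was 7.74. The strongest lay in the cluster on chromosome 13, at 23585708 to 23586335 and at 23574013 to 23574470. The first (26.8-fold) was assigned to Hist1h2be and Hist1h4d, 35103 and 4423 bp downstream of their TSSs. The second (23.9-fold) was assigned to Hist1h2ad, Hist1h2ae and neighbours, 140 bp upstream of the TSS of Hist1h2ad. By class, 13 of 16 H2A, 13 of 17 H2B and 8 of 11 H3 genes had a peak within 1 kb of the TSS, against 3 of 13 H4 and 0 of 5 H1 genes.

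**Figure D4:**
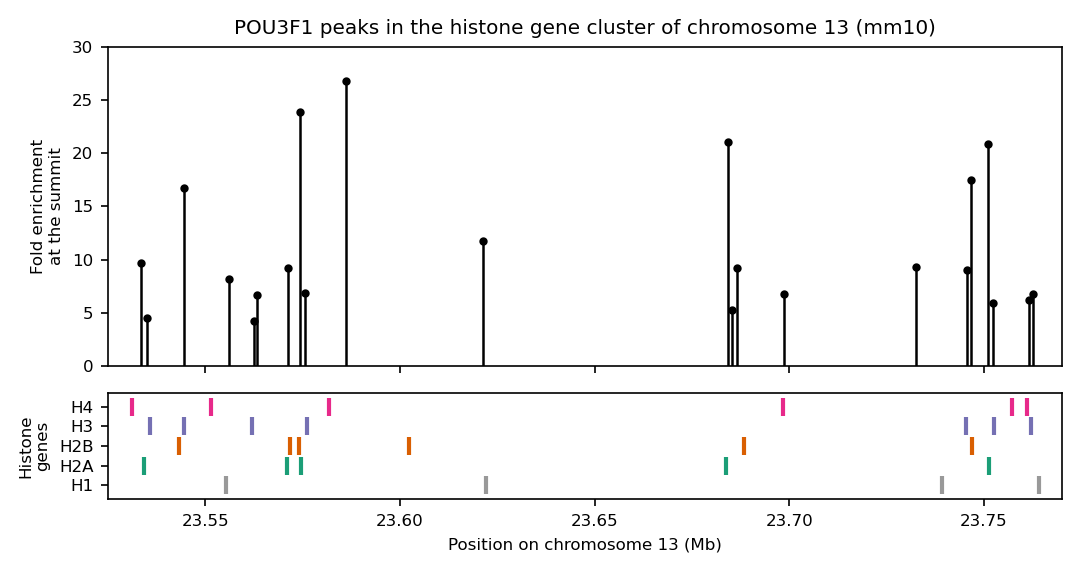
POU3F1 peaks (upper panel, fold enrichment at the summit, y axis) along the histone gene cluster of chromosome 13 (x axis, Mb, mm10), with the midpoints of H1, H2A, H2B, H3 and H4 genes below. The highest peak of the region reaches 26.8-fold.

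Cytosolic ribosomal protein genes, another highly transcribed class, had a peak in 9 of 76 cases (11.8%) against 4.94 expected, a ratio of 1.82 (exact permutation test, adjusted p = 0.136). None of them had a peak within 1 kb of the TSS. Their strongest peaks lay 48443 bp downstream of Rpl14 (30.5-fold), 157479 bp downstream of Rplp1 (24.7-fold), 55270 bp upstream of Rpl31 (18.5-fold) and 44394 bp downstream of Rps24 (10.4-fold). A Fisher's exact test of histone against ribosomal protein genes with a peak gave p = 3.25e-16. Histone genes that share peaks were counted singly in it, so this p-value rests on fewer independent units than genes.

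Chromosome X had few peaks. It had 43, or 0.252 per Mb of annotated span, against 1.04 per Mb over the autosomes, a ratio of 0.241 (95% exact interval 0.175 to 0.325), and the lowest autosome had 0.751 per Mb. Per 100 protein-coding genes it had 4.45 peaks (3.22 to 6.0), against 5.62 on the lowest autosome, chromosome 7, and 21.4 on the highest, chromosome 3. The strongest named peak on X was that of Tenm1.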

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

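These peaks or genes carried signal outside the main comparisons, and the test of small nuclear RNA genes was chosen after the data were seen. On 5 unplaced or unlocalised contigs lay 43 peaks, 33 of them on a single contig, with a median fold of 1.51 over all 43 against 6.39 on the autosomes and X. On the mitochondrial sequence, 1 peak of 16276 bp ran from 18 to 16293 (12.4-fold) and is part of the total length covered. No filter for regions prone to artifacts was applied to the peak list here. Chromosome Y held 14 peaks, 0.154 per Mb of annotated span, as many as the unplaced peaks of Erdr1. Small nuclear RNA genes on the autosomes and X overlapped a peak in 15 of 1003 cases, and 15 peaks overlapped such a gene where random placement gave 0.539 (permutation test, p = 0.0020, the smallest possible). Gm23287 (22.1-fold), Rnu3a (8.29-fold), Rnu11 (4.13-fold) and Rnu1a1 (4.09-fold) were among them.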

How the results depend on the processing

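No paired analysis was possible because there was 1 library per antibody. The motif and octamer tests and their alternatives were not run, since no sequence was used here. Dropping contigs, Y and mitochondrial peaks, and dropping histone genes from the background, were chosen after seeing the data; neither these nor 20 strata moved a list result across its threshold or turned its direction, and a q-value under 0.01 moved no location or list result so. The overlap of the interval lists was 2652 under each overlap rule. POU, amacrine and horizontal, progenitor and histone genes passed under all alternatives run.

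Widening the TSS window to 5 kb took 177 peaks to 290. It took the ratio near gene ends to 1.04, with fewer peaks than random placement gave outside the 1 kb window. Without strata the contralateral list reached 4.36 and the ipsilateral list 2.80, both past the threshold. With all annotated genes as background, the contralateral (7.48), ribosomal (5.58), ipsilateral (5.23), photoreceptor (4.39) and endothelial (4.22) ratios passed, and Schwann (1.26) and liver and muscle (1.79) rose above 1 without passing; this background holds many genes with few peaks. With the nearest TSS within 50 kb, SOX (3.26), pigment epithelium and lens (3.23) and adhesion (2.08) ratios no longer passed, while Schwann (1.60) and endothelial (0.956) crossed 1. With peaks within 5 kb of the TSS alone, 4 lists passed; Notch (6.68), RGC identity (4.66), SOX (3.10), guidance (3.02), pigment epithelium and lens (2.12) and adhesion (2.0) did not, and the contralateral, ipsilateral, ribosomal and endothelial ratios were 0. These assignments leave fewer genes with a peak; the cause was not tested further. Peak counts were redone within 50 kb for 23 genes only (Pou3f1, those with the most peaks, contralateral and ipsilateral members): 22 moved, and that of Pou3f1 (2 peaks) did not. Low pileups limit single peaks, and the missing replicate limits all of them.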

Other observations

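The gene families in this paragraph and all tests in this part except the summits inside histone genes and those of chromosome X were chosen after the results were seen. All 6 Iroquois homeobox genes (Irx), transcription factors of neural patterning, had a peak, a count given without a test because 4 of them had been seen in the RGC identity list and neighbours such as Irx3 and Irx5 shared peaks, the strongest of them at chromosome 8: 92133914 to 92134462 (12.1-fold). Olfactory receptor genes had a peak in 6 of 1110 cases against 42.5 expected from loci of matched length, a ratio of 0.141 (exact permutation test, adjusted p = 4.1e-12 over 7 families). Neighbouring genes of this family were counted singly, so this p-value may rest on fewer independent units than genes. How well reads map to these genes was not examined. Forkhead genes (11 of 44, ratio 1.67), Hox genes (4 of 39, ratio 2.38), TLE corepressor genes (3 of 7, ratio 2.29), zinc-finger genes (27 of 397, ratio 0.869) and solute carrier genes (47 of 375, ratio 1.34) did not pass, with adjusted p from 0.0784 to 0.480. Windows of 1 Mb with many peaks were the histone cluster at 23000001 to 24000000 on chromosome 13 (22 peaks), 3000001 to 4000000 on chromosome 9 (18 peaks, none above 5.29-fold), and 83000001 to 84000000 on chromosome 13 around Mef2c (17 peaks). Whether the window on chromosome 9 holds repeat sequence was not examined.

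POU3F1 peaks at histone genes could reflect open or highly transcribed promoters in general, reads shared between near-identical copies, or octamer elements, a POU binding site known from H2A and H2B promoters. Of 34 summits near histone genes, 6 lay inside such a gene, 17.6% (exact interval 6.76 to 34.5%), where shared coding reads would put most of them. Ribosomal protein genes had a peak in 11.8% of cases against 79.0% of histone genes (Fisher's exact p = 3.25e-16, with genes that share peaks counted singly). When histone genes within 1 kb of each other count as 1 unit, 81.0% of 42 units had a peak, though neighbouring units can still share one. Both histone shares lie above that of ribosomal protein genes. This argues against high transcription as the whole cause, as far as ribosomal protein genes stand for it. Openness of promoters was not measured and other active promoters were not compared, so open promoters in general were not tested as a cause. Of these units, 18 of 22 with an H2A or H2B gene and 6 of 20 without had a peak within 1 kb of a TSS, but the former often hold more genes, and among units of 1 gene the shares, 4 of 7 and 5 of 19, did not differ past the threshold (Fisher's exact p = 0.188), so octamers at H2A and H2B promoters stay open. They would not be the only source, since 8 of the 11 H3 genes were themselves the nearest TSS of a peak within 1 kb. The octamer was not searched, a nonspecific affinity of the antibody stays open, and no biological explanation was tested against the IgG library.

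The low peak density of chromosome X, 0.241 of the autosomal one, could come from fewer genes or from a single copy in male embryos. The peaks per 100 genes, 4.45, had an interval reaching 6.0, above chromosome 7, so by that measure the part of gene number stays open. Yet every autosome with fewer protein-coding genes than the 966 of X had more peaks than its 43, a comparison added after seeing the results. These autosomes ranged from 78 peaks on chromosome 15 to 173 on chromosome 13, which argues against fewer genes as the whole cause. With pileup and control at 50%, 67.3% of autosomal peaks would still pass by calculation, while the interval of the X ratio ended at 0.325. If peaks on X are otherwise like autosomal ones, which was not tested, this argues against a single copy as the whole cause. Both together were not tested, and the sex of the embryos is not given. No biological explanation was tested for this pattern.

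The local background recovered for each peak may come from a control track scaled to the POU3F1 library. Among 1781 peaks with a background above its floor and under 20, 76.1% lay at whole multiples of 0.514, against 1% of uniform values within the same tolerance (0.005 of the step), and 786 peaks (30.1%) sat at the floor of 1.04. This is consistent with peak calling against a scaled control, possibly the IgG library, whose use is not stated in the sources used here. No biological explanation was tested for this pattern.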
